A study of Bos taurus with 14 samples.

How the data were processed

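Total RNA of 14 cattle samples was sequenced after library preparation with a TruSeq RNA kit: 10 stem cell libraries (CTFR-bESC lines A and B, 5 passages each), 2 pools of 10 blastocysts and 2 skin fibroblast lines. The authors deposited 1 file per library with RPKM values, read counts divided by gene length and by the library's mapped reads, and no read counts themselves. The genome build UMD3.1 and the tool edgeR appear in the submitters' processing notes; their roles and versions, the aligner, the read counter and the gene annotation are not given in the sources used here. Nothing states which reads entered the library total or that all files were made in 1 run.

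The files fall into 2 sets. The 6 control and P10 files share 1 list of features, of which 26 had an unreadable name, 25 a date in place of a name and 21 a blank value; these were left out and 23159 were used. The 8 later files share another list, in which 26 names had turned into date numbers in 5 files and were restored from the others. The sets have 21008 names in common; 2568 with a numbered copy suffix were left out, because nothing shows that a number marks the same copy in both, and 18440 were used. A table of bovine reference gene symbols matched 15004 names of the first set and 15599 of the second, and 13755 of the shared names. It gives no coordinates for these names, so positions are left out.

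Without counts, depth in reads is unknown, and no counting interval or detection limit is given. From the ratio of low values, which shows what 1 read is worth, depth relative to fibroblast line 1 was about 1.0 to 1.556 in the first set, and 0.71 to 1.027 of line A at P13 in the second. A value of 0 is written as listed at 0. No fold change is given against a group listed at 0, but such genes enter list counts and medians with a fitted change that depends on the pseudocount.

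Values were tested as log2(RPKM + 1), which understates changes of genes near or under 1 RPKM. Genes with at least 1 RPKM in at least 2 libraries of a fit were kept. Each gene was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, two-sided, and a Benjamini-Hochberg adjusted p under 0.05 was the call. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The first fit holds the 2 P10, 2 blastocyst and 2 fibroblast libraries as 3 groups with 1 common spread. The second holds the 10 stem cell libraries with terms for line, passage number and P10. It gives the line difference, the slope per 10 passages among later passages and the step at P10. With a line by passage term it gives the difference of slopes. The lines share the P10 term, so the gap between lines at P10 also enters the difference of slopes. The comparisons with blastocysts and with fibroblasts share the P10 libraries, so they are not set against each other. No count test was run, because reads cannot be recovered from RPKM without gene lengths.

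Where another scaling moved the median of all genes by over 0.1 log2, changes are given relative to the median gene of that comparison. The median gene stood at 0.23 against fibroblasts, 1.43 against blastocysts and -0.11 for the P10 step. The p-values and calls test the fitted change before that subtraction. Standard errors (SE) are those of the fit; means are given with the SD.

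The 22 gene lists covered core pluripotency, naive-state and primed-state genes, trophectoderm, hypoblast, mesoderm and primitive streak, neural ectoderm, fibroblast and mesenchyme, epithelial junction, keratinocyte, blood and immune cell and germline markers, targets of WNT, FGF and ERK, NODAL and TGF-beta, and p53, and genes of DNA methylation and polycomb, cell cycle, glycolysis, oxidative phosphorylation, imprinting and the mitochondrial genome. Each was tested against all other genes with camera of limma, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The lists, the fits, the filter, the named-gene rule and all alternatives but the 5 named next were fixed before the data were examined. Chosen after seeing the data were 5 alternatives (names shared by both sets, scaling without the 2 most abundant features, leaving out line A at P13 and P35 in either fit, and the 8 later libraries alone) and 3 further lists, for cholesterol synthesis, hypoxia and immediate early genes.

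Genes were named by rule. Per comparison the rule takes the 8 called genes with a symbol and the largest change in each direction, a mean of at least 10 RPKM in the higher group and the same direction in every between-group pair. It adds up to 4 members of each list with the smallest adjusted p, up to 2 members with the highest mean RPKM of a list without a call, and POU5F1, SOX2 and NANOG. Features named outside it were chosen after their values were seen. Some genes are not reported here, although the rule names them or their direction reversed under another scaling; they stay in the list tests and in the gene counts.

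Alternatives tried were a pseudocount of 0.1, no filter and a filter at 5 RPKM, quantile normalization, median-of-ratios scaling, no mean-variance trend, other sets of stem cell libraries, line means over the 5 passages, no P10 term, log2 passage, each line alone, blocks by replicate letter or passage stage, an estimated correlation and leaving out each library in turn. The fits were checked on simulated data with the same design. The spread followed mean expression in the real fit and was drawn independently for each gene and library, so differences that genes share between libraries were not simulated. Among 100 changed genes, 83% of changes of log2 1 were recovered against fibroblasts and 86% against blastocysts, 74% of line differences of 0.5, 88% of slopes of 0.25 per 10 passages, 38% of slope differences of 0.25 and 99% of P10 steps of 1.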

Results

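Total RNA was sequenced from 14 cattle samples. The subject was a bovine embryonic stem cell culture, CTFR-bESC, derived from blastocysts. The cells grew on mouse embryonic fibroblast feeders in a growth factor-free base medium supplemented with FGF2 and with IWR1, a small molecule that blocks WNT signalling. Line A was sampled at passages 10, 13, 23, 35 and 45 and line B at passages 10, 12, 24, 35 and 46, with 1 library each. The controls were 2 pools of 10 whole blastocysts and 2 lines of skin fibroblasts. Libraries of 1 line are serial passages of 1 culture. In the fit of the 10 stem cell libraries, p-values thus measure the spread between passages and not between independently derived cultures. The fit against the controls has only 2 libraries per group, from 2 stem cell lines, 2 blastocyst pools and 2 fibroblast lines. Its p-values measure the spread between these samples.

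The deposited values are RPKM per gene, with no read counts, so the depth of each library is unknown in reads. The files come in 2 sets with different lists of features: the controls and P10 in the first and the 8 later libraries in the second. Summed RPKM ran from 349527 to 435754 in the first set and from 475822 to 501373 in the second. Features at 1 RPKM or more numbered 7558 and 7447 in the blastocyst pools, 10071 and 10023 in the fibroblasts, 10708 in line A and 11205 in line B at P10, and 12152 to 12563 in the later libraries. A pair of features without a gene name in the table used, ENSBTAG00000043570 and ENSBTAG00000043567, took 65.8% and 64.0% of the summed RPKM in blastocyst pools 1 and 2; they were chosen after their values were seen. In the other libraries the top 2 features took 2.1% to 3.4%. GAPDH was listed at 0 in all 14 libraries, so a value of 0 can be a failed estimate and is written here as listed at 0.

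The blastocysts, the fibroblasts and the stem cells formed 3 separate groups. On the first principal component (61.9% of the variance over the genes shared by all files) the blastocyst pools stood at 177.19 and 179.73 and the fibroblasts at 39.39 and 41.97. On the second (26.6%) the fibroblasts stood apart at 126.47 and 121.05. Across 11307 genes, which are not independent replicates, Pearson correlations of log2 values were 0.959 between the P10 libraries, 0.968 to 0.997 among the later libraries and 0.887 to 0.934 between these sets. They were 0.627 to 0.664 between P10 and blastocyst libraries and 0.677 to 0.715 between P10 and fibroblast libraries. Among the 8 later libraries alone, line A at P13 and P35 stood at 33.24 and 26.6 on the first component (52.5%) and line B at P35 at 7.53, while the other 5 lay between -6.85 and -19.38.

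**Figure D1:**
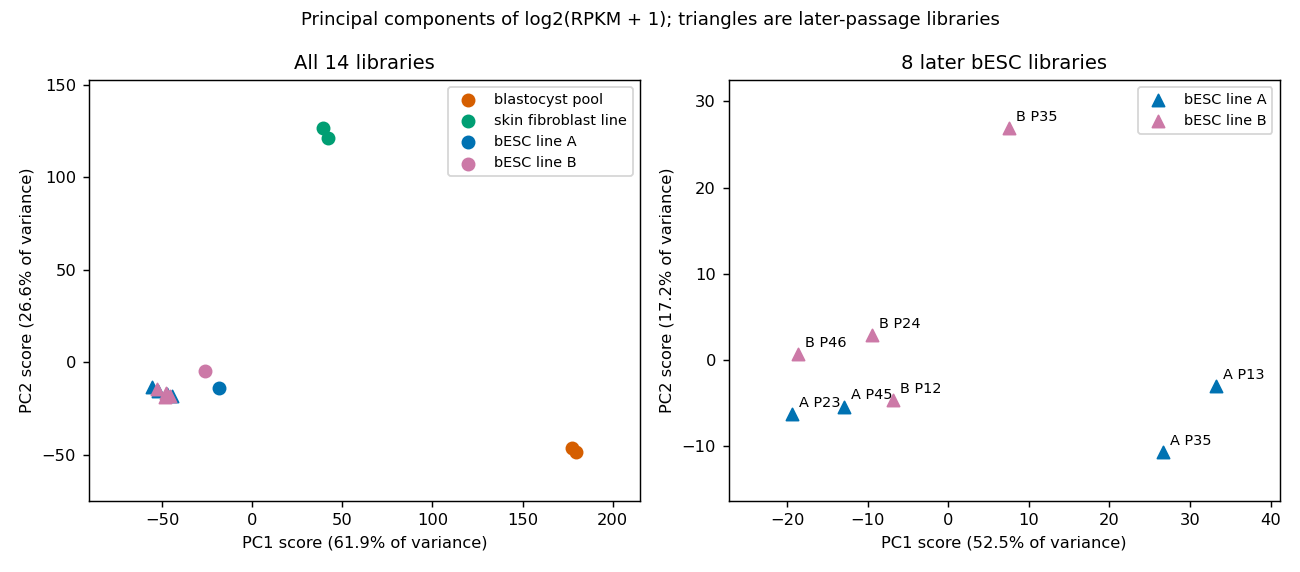
Principal components of log2(RPKM + 1), unitless scores, with 1 point per library; the first panel shows all 14 libraries and the second the 8 later stem cell libraries. In the first panel the blastocyst pools stand at 177.19 and 179.73 on the first component, and in the second line A at P13 and P35 stand at 33.24 and 26.6.

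The first comparison asks which genes separate early stem cells from a differentiated cell. Most core pluripotency genes were higher at P10 than in fibroblasts. POU5F1, a transcription factor of pluripotent cells, measured 223 RPKM in line A and 151 in line B and was listed at 0 in both fibroblast lines. SOX2, its partner on DNA, rose from 1.03 ± 1.1 to 150 ± 2.57 RPKM (SD, n = 2), a log2 change of 6.09 ± 0.38 (SE) relative to the median gene. Here and in the other comparisons p-values test the fitted change before subtraction of the median gene, which for SOX2 was 6.32 (adjusted p = 5.28e-05). NANOG was low, at 4.49 and 2.15 RPKM in lines A and B and listed at 0 in fibroblasts; its call (adjusted p = 0.0216) was lost under quantile normalization (0.0862) and median-of-ratios scaling (0.0681). Most fibroblast and mesenchyme genes fell: the fibril collagen gene COL1A1 measured 47.9 ± 16.2 RPKM at P10 and 1635 ± 100 in fibroblasts, a change of -5.33 ± 0.25. Among the largest changes, STMN2, a neuronal regulator of microtubules, measured 517 and 401 RPKM and was listed at 0 in all 4 controls, and IRS4, an insulin receptor substrate, rose by 7.63 ± 0.20. The peptide hormone gene SST stood at -9.72 ± 0.20 and the matrix protein gene TNC at -8.25 ± 0.74.

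Of 11 tested core pluripotency genes, 9 were called higher, 8 of them under every scaling, and 0 lower, with a median change of 4.39 relative to the median gene. DNMT3B, a DNA methyltransferase of early embryos, rose by 5.84 ± 0.27 to 88 ± 28.9 RPKM. SALL4 measured 58.2 and 51.5 RPKM in lines A and B and was listed at 0 in fibroblasts. The list stood out against other genes in the camera test (adjusted p = 5.82e-04), a call that ended with adjusted p = 0.413 with an estimated correlation. Primed-state genes, those of the later epiblast, rose in 9 of 10 cases and fell in 1, THY1, with a median of 4.98 (adjusted p = 5.82e-04, and adjusted p = 0.413 with an estimated correlation). THY1, chosen after its values were seen, measured 0.89 and 2.62 RPKM in lines A and B and 297 and 241 in the fibroblast lines. OTX2 stood at 139 and 121 RPKM against values listed at 0 in fibroblasts, and ZIC2 rose by 6.67 ± 0.19 and HMGA2 by 5.20 ± 0.19. Of 10 naive-state genes, 1 rose and 2 fell (adjusted p = 0.311), with KLF4 at -4.23 ± 0.28, TBX3 at -2.33 ± 0.27 and SUSD2 at 2.27 ± 0.38.

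The fibroblast and mesenchyme list moved together, with 20 of 21 members lower and 0 higher, at a median of -4.70 (adjusted p = 1.52e-12, and adjusted p = 0.413 with an estimated correlation). ACTA2, a smooth muscle actin, stood at -6.94 ± 0.21, the protease FAP at -4.70 ± 0.19 and the receptor PDGFRB at -3.97 ± 0.19. Line B carried more of this list at P10 than line A, with a mean log2(RPKM + 1) of 4.03 against 2.86. Epithelial junction genes rose in 7 of 11 cases and fell in 0 (median 1.37, adjusted p = 0.0194, and adjusted p = 0.413 with an estimated correlation). CLDN6, a tight junction claudin, changed by 5.29 ± 0.20 and the desmosome protein DSP by 4.06 ± 0.33, while EPCAM measured 8.23 and 7.65 RPKM against values listed at 0.

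All 18 cell cycle genes rose, at a median of 1.49 (adjusted p = 7.34e-05, and adjusted p = 0.413 with an estimated correlation), among them the replication helicase genes MCM2 at 2.55 ± 0.25 and MCM5 at 2.45 ± 0.25 and the mitotic kinase AURKB at 1.76 ± 0.19. All 11 DNA methylation and polycomb genes were called higher, 10 of them under every scaling, at a median of 1.66 (adjusted p = 8.65e-04, and adjusted p = 0.465 with an estimated correlation), with JARID2 at 5.04 ± 0.18, DNMT3A at 3.66 ± 0.21 and TET1 at 3.52 ± 0.31. Imprinted genes rose in 8 of 11 cases and fell in 2 (median 2.07, adjusted p = 0.082): NNAT changed by 6.75 ± 0.40, PEG10 by 4.73 ± 0.22 and MAGEL2 by 4.50 ± 0.19. This list passed camera under quantile normalization (adjusted p = 0.0338) and median-of-ratios scaling (0.0383).

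The remaining lists did not pass camera, whose adjusted p is given in parentheses. Trophectoderm genes split 3 higher and 4 lower of 14 (0.527), with the keratins KRT18 at 5.09 ± 0.21 and KRT19 at 4.55 ± 0.49 against TFAP2A at -3.88 ± 0.35. Hypoblast genes split 2 and 4 of 8 (0.299), with APOA1 at 3.21 ± 0.25 and PDGFRA at -4.73 ± 0.32. Mesoderm genes split 2 and 2 of 4 (0.717), with BMP4 at -2.84 ± 0.28, and neural ectoderm genes 3 and 0 of 4 (0.166), with the tubulin TUBB3 at 2.57 ± 0.34. WNT target genes split 3 and 0 of 3 (0.136), led by NKD2 at 1.96 ± 0.17. FGF and ERK target genes split 7 and 2 of 14 (0.85), with DUSP4 at 3.74 ± 0.47 and ETV5 at 2.02 ± 0.20 against IER3 at -4.41 ± 0.35, and NODAL and TGF-beta target genes 3 and 2 of 5 (0.754). Glycolysis genes split 3 and 5 of 12 (0.311), with the glucose transporter SLC2A1 at 2.11 ± 0.16 and PGK1 at -1.26 ± 0.16. PGK1 stood at 0.50, also relative to the median gene, when the 8 later libraries stood in for P10. Oxidative phosphorylation genes split 1 and 3 of 11 (0.311), with COX6C at -1.10 ± 0.18. Germline genes split 1 and 0 of 3 (0.572), p53 target genes 0 and 3 of 10 (0.104, with CDKN1A at -2.85 ± 0.26), keratinocyte genes 0 and 1 of 4 (0.387), blood and immune cell genes 2 and 1 of 4 (0.93) and mitochondrially encoded genes 0 and 1 of 6 (0.664).

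Of 11761 genes tested against fibroblasts, limma called 4160 higher and 2576 lower, 61.8% of the calls higher; 3056 and 1798 of these changed at least 2-fold. The median gene stood at 0.23 log2, and at 0.04 under quantile normalization and 0.06 under median-of-ratios scaling. Under all 3 scalings 3022 genes were called higher and 2498 lower, and 0 were called in opposite directions. Adjusted over the list alone, the counts differed from the above in 5 lists: FGF and ERK target 7 and 3, oxidative phosphorylation 1 and 2, germline 2 and 0, keratinocyte 0 and 0, mitochondrially encoded 0 and 0. The naive-state and trophectoderm lists each had a median of 0 before the shift, with means of -0.41 and 0.38 and a camera direction of down, and the NODAL and TGF-beta target list had a median of 0.78, a mean of -0.64 and a camera direction of down. The higher count was 2426 without line A at P10 and 2695 without line B at P10, and the lower count 1691 without fibroblast line 1.

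**Figure D2:**
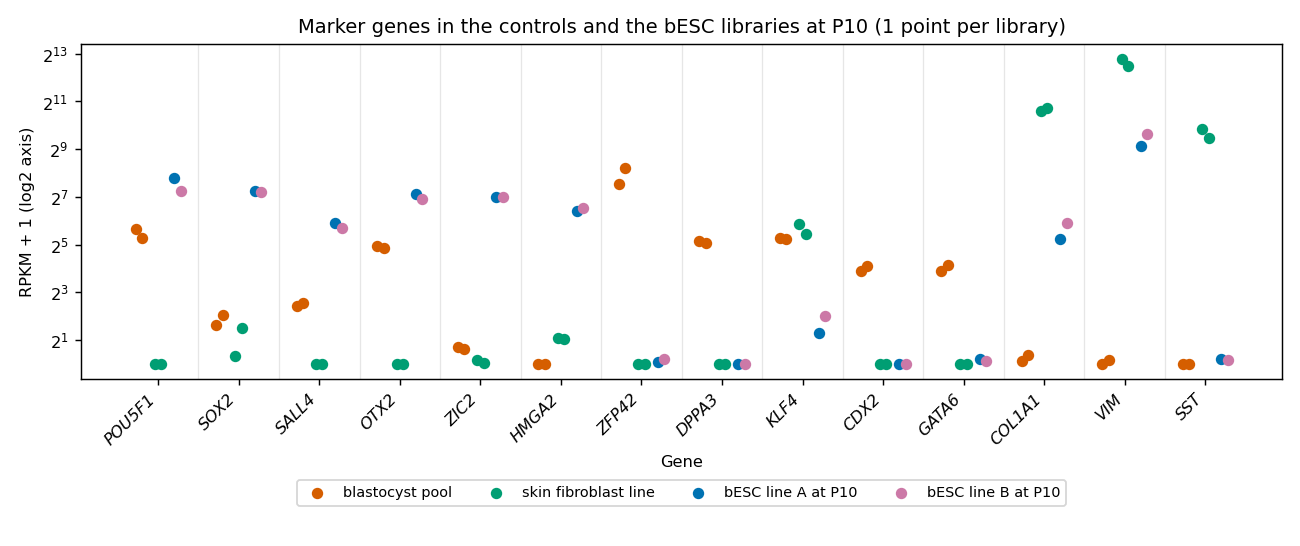
RPKM + 1 on a log axis for 14 genes in each blastocyst, fibroblast and P10 stem cell library, 1 point per library. POU5F1 stands at 223 and 151 RPKM in the stem cells and is listed at 0 in the fibroblasts, and VIM averages 674 RPKM in the stem cells, 0.055 in blastocysts and 6400 in fibroblasts.

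The second comparison sets P10 stem cells against whole blastocysts, the embryo stage they came from, in which epiblast, trophectoderm and hypoblast are mixed. Most naive-state and trophectoderm genes were lower in the stem cells, while primed-state and imprinted genes were higher. ZFP42, a marker of naive pluripotent cells, measured 0.102 ± 0.0757 RPKM at P10 and 240 ± 76.8 in blastocysts (SD, n = 2), a change of -9.16 ± 0.26 (SE) relative to the median gene. DPPA3 measured 34.6 and 32.3 RPKM in the blastocyst pools and CDX2, a trophectoderm transcription factor, 13.8 and 15.9; both were listed at 0 in the P10 libraries. POU5F1 rose from 43.4 ± 7.37 to 187 ± 50.8 RPKM, by 0.64 relative to the median gene and by 2.06 ± 0.24 as fitted (adjusted p = 2.38e-04), and SOX2 from 2.65 ± 0.754 to 150 ± 2.57, by 3.95 relative to the median gene and 5.38 ± 0.38 as fitted (adjusted p = 3.41e-05). NANOG measured 0.549 and 4.57 RPKM in the pools against 4.49 and 2.15 in lines A and B and was not called (adjusted p = 0.447). Among the largest changes, the growth factor PTN rose by 6.87 ± 0.70 and the cell surface proteoglycan GPC4 by 6.62 ± 0.20, while the phosphate transporter SLC34A2 stood at -7.58 ± 0.19 and the aminopeptidase ENPEP at -7.47 ± 0.19.

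Of 10 naive-state genes, 9 fell and 0 rose under every scaling, with a median of -4.58 (adjusted p = 5.01e-18, and adjusted p = 0.0863 with an estimated correlation). ESRRB stood at -4.52 ± 0.18 and TBX3 at -5.74 ± 0.27. All 10 primed-state genes were called higher, 9 of them under every scaling, at a median of 3.73 (adjusted p = 0.0166, and adjusted p = 0.269 with an estimated correlation). SALL2 changed by 5.50 ± 0.24, ZIC2 by 4.91 ± 0.19 and ZIC5 by 3.83 ± 0.19, while HMGA2 measured 84.8 and 92.3 RPKM in lines A and B and was listed at 0 in blastocysts. Core pluripotency genes were called higher in 8 and lower in 2 of 11 cases (5 and 2 under every scaling), with SALL4 at 1.89 ± 0.19 and UTF1 at 1.46 ± 0.15 among those higher. The other gene lower besides ZFP42 was DPPA2, listed at 0 at P10. The list did not pass camera (adjusted p = 0.524), where its direction was down although its relative median was 0.28.

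Trophectoderm genes fell in 9 of 14 cases under every scaling (median -3.74, adjusted p = 7.75e-14, and adjusted p = 0.0863 with an estimated correlation); 2 were called higher as deposited and 0 under every scaling. GATA3 changed by -5.03 ± 0.18 and KRT18 by -4.53 ± 0.21. Hypoblast genes were called higher in 2 and lower in 3 of 8 cases (median -2.36, adjusted p = 1.19e-04, and adjusted p = 0.11 with an estimated correlation). The endoderm regulators GATA6 at -5.26 ± 0.18 and HNF4A at -2.84 ± 0.13 fell while the apolipoprotein APOA1 rose by 3.47 ± 0.25; under quantile normalization the list had an adjusted p of 0.0506. Epithelial junction genes were called lower in 8 of 11 cases and higher in 3 (median -2.59, adjusted p = 3.88e-09, and adjusted p = 0.11 with an estimated correlation). These included the splicing regulator ESRP1 at -5.80 ± 0.20, EPCAM at -4.06 ± 0.18 and the epithelial transcription factor GRHL2 at -3.79 ± 0.14. Keratinocyte genes fell in 3 of 4 cases (adjusted p = 1.19e-04, and adjusted p = 0.196 with an estimated correlation), with KRT5 at -5.09 ± 0.61 and DSG3 at -3.75 ± 0.17. Germline genes fell in 2 of 3 cases (adjusted p = 1.28e-04, and adjusted p = 0.11 with an estimated correlation), with MAEL at -2.67 ± 0.20 and TDRD1 listed at 0 at P10.

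Fibroblast and mesenchyme genes were called higher in 16 of 21 cases and lower in 0, 11 and 0 under every scaling, at a median of 0.79. The intermediate filament VIM measured 674 ± 172 RPKM against 0.055 (0 and 0.11 in the pools), the gelatinase MMP2 90.2 ± 31.7 against 0.044 and COL1A1 47.9 ± 16.2 against 0.184 ± 0.135; in fibroblasts COL1A1 stood at 1635 ± 100. As deposited the list did not pass camera (adjusted p = 0.297), but it did under median-of-ratios scaling (0.00831) and quantile normalization (0.00299). All 11 imprinted genes were called higher, 8 of them under every scaling, at a median of 1.60 (adjusted p = 0.0539 as deposited, 0.00467 and 0.00149 under the same scalings). NNAT changed by 6.96 ± 0.40, MEST by 6.06 ± 0.87 and PEG10 by 5.55 ± 0.22. Neural ectoderm genes were called higher in 4 of 4 cases under every scaling (adjusted p = 0.161 as deposited, 0.041 and 0.0186 under the same scalings), with TUBB3 at 3.20 ± 0.34 and the intermediate filament NES at 2.41 ± 0.40.

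Targets of the FGF and ERK pathway were called higher in 11 of 14 cases, 7 under every scaling, and lower in 0 (median 0.79, adjusted p = 0.524), with the feedback genes ETV5 at 3.39 ± 0.20 and SPRY1 at 3.31 ± 0.27. Cell cycle genes were called higher in 15 of 18 cases, 10 under every scaling (median 0.57, adjusted p = 0.258), with MCM2 at 2.88 ± 0.25. DNA methylation and polycomb genes were called higher in 6 and lower in 1 of 11 cases, 3 and 1 under every scaling (0.614); the maintenance methylation genes UHRF1 and DNMT1 changed by 3.42 ± 0.40 and 2.04 ± 0.24. Of 12 glycolysis genes 7 were called higher and 1 lower, 3 and 1 under every scaling (0.669), with PFKM at 2.50 ± 0.22. For oxidative phosphorylation 8 of 11 genes were called higher and 1 lower as deposited, but 0 and 1 under every scaling: the changes of ATP5A1 and NDUFS1 were positive as deposited and negative under both other scalings, while relative to the median gene they stood at -0.24 and -0.66 as deposited and were negative under all 3. Its median was -0.67 relative to the median gene (adjusted p = 0.484, and 0.0036 with direction down under median-of-ratios scaling). Mesoderm genes split 1 higher and 0 lower of 4 (0.128), WNT target genes 2 and 0 of 3 (0.785, with NKD2 at 7.61 ± 0.131 RPKM and listed at 0 in blastocysts), NODAL and TGF-beta target genes 2 and 0 of 5 (0.358, none under every scaling). p53 target genes split 7 and 0 of 10 (0.879, with BAX at 2.23 ± 0.29), blood and immune cell genes 1 and 1 of 4 (0.0949) and mitochondrially encoded genes 2 and 2 of 6 (0.0692, with ND5 at -2.72 ± 0.33 and ATP8 at 1.33 ± 0.28).

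Of 11761 genes tested against blastocysts, limma called 8583 higher and 862 lower, 90.9% of the calls higher, and 7425 and 635 changed at least 2-fold. This split rests on the scaling: 3508 higher and 3546 lower (49.7% higher) under quantile normalization, and 5168 and 2481 (67.6%) under median-of-ratios scaling. The median gene stood at 1.43 log2 as deposited and at -0.01 and 0.48 under those scalings. Under all 3, 3469 genes were called higher and 862 lower, and 900 were called one way as deposited and the other way under another scaling. Counts adjusted over the list alone were the same for all 22 lists. The DNA methylation and polycomb and p53 target lists had a positive relative median (0.11 and 0.17) and a camera direction of down, and the mesoderm list had a median of -0.15 and a mean of 0.12 as deposited. The lower count was 489 without blastocyst pool 1 and 433 without pool 2.

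The third comparison asks whether the lines differ once passage and the P10 step are accounted for. Few genes were called between them. SOX2 averaged 168 ± 21.9 RPKM in line A and 168 ± 15.3 in line B (SD, n = 5), VIM 623 ± 62 and 655 ± 140, and HMGA2 108 ± 23 and 124 ± 26. SYCP3, a protein of meiotic chromosome axes, averaged 5.19 ± 1.96 RPKM in line A and 15.2 ± 7.86 in line B and was higher in line B at each of the 5 stages, with a log2 difference of 1.27 ± 0.17 (SE) and an adjusted p of 0.0598, just short of the call. DNMT3B stood at 126 ± 21.5 and 107 ± 34.6 RPKM (adjusted p = 0.498), and SNRPN, an imprinted gene, at 220 ± 48.3 and 170 ± 33.8 (adjusted p = 0.177).

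The 2 features called, ENSBTAG00000001836 and ENSBTAG00000046595, were higher in line B and have no symbol in the files; they were chosen after their values were seen. The former ranged from 0 to 0.326 RPKM in line A and from 2.26 to 8.02 in line B (log2 difference 2.15 ± 0.23), the latter from 0.094 to 0.276 and from 1.12 to 2.65 (1.18 ± 0.13), each with an adjusted p of 0.031. Of 10726 genes, limma called 2 higher and 0 lower in line B, against 521 and 681 at an unadjusted p under 0.05. The few calls do not show that few genes differ. In simulated data 74% of line differences of log2 0.5 were recovered, with a spread independent between genes and libraries. KRT19 differed by 0.98 ± 0.30 in the real data without a call (limma adjusted p = 0.431), so that share may overstate recovery. Leaving out line A at P10 or line B at P10 left 1 call, and leaving out line A at P13, P23, P35 or P45 or line B at P12, P24 or P46 left 0. With passage stage as a block limma called 0 genes, against 568 and 871 at an unadjusted p under 0.05.

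Without a called gene in any list, 3 lists were higher in line B by camera. These were p53 target genes at a median log2 of 0.27 (adjusted p = 1.67e-04, and adjusted p = 0.311 with an estimated correlation), fibroblast and mesenchyme genes at 0.22 (adjusted p = 0.00502, and adjusted p = 0.819 with an estimated correlation) and FGF and ERK target genes at 0.22 (adjusted p = 0.00502, and adjusted p = 0.311 with an estimated correlation). The fibroblast and mesenchyme difference lay at P10, with a list mean log2(RPKM + 1) of 2.86 in line A and 4.03 in line B. In the later libraries the lines overlapped, at 4.18 to 4.64 in line A and 4.06 to 4.44 in line B. Adjusted over the list alone, limma called 9 genes higher and 2 lower in line B. The former were SUSD2 (naive-state), KRT19 (trophectoderm), DUSP6 and SPRY4 (FGF and ERK target), IGF2R (imprinted), SYCP3 (germline), GADD45A and ZMAT3 (p53 target) and KRT10 (keratinocyte); the latter were SNRPN and NDN (imprinted). Of these, KRT19, SPRY4, IGF2R, GADD45A, ZMAT3 and NDN were chosen after their values were seen. Of these, GADD45A differed by 0.76 ± 0.22, SPRY4 by 0.67 ± 0.18 and NDN by -0.67 ± 0.18. The other testable lists did not pass camera, with adjusted p from 0.0975 for DNA methylation and polycomb to 0.969 for primed-state and glycolysis. The primed-state list had a median of -0.06 and a mean of 0.01 with direction up, the glycolysis list -0.05 and -0.10 with direction up, and the imprinted list -0.08 and 0.01 with direction down. Germline, keratinocyte and blood and immune cell lists had 2, 1 and 2 tested members, too few for camera.

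The fourth comparison asks whether expression drifts with passage, from P12 to P46, and whether the lines drift apart. No pluripotency gene that could be tested was called: SOX2 changed by -0.07 ± 0.03 log2 per 10 passages (SE, 10 libraries, adjusted p = 0.99), ZIC2 by -0.01 ± 0.05 and DNMT3B by -0.12 ± 0.08. The keratin KRT8 changed by 0.24 ± 0.11 and the lactate dehydrogenase LDHA by 0.25 ± 0.21, neither called. POU5F1 and NANOG were not among the names shared by both sets of files and are not analysed here beyond P10.

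Glycolysis genes stood out together, at a median of 0.18 per 10 passages (camera adjusted p = 1.18e-05, and adjusted p = 0.583 with an estimated correlation). Glycolysis varied between libraries of 1 stage too. Its mean log2(RPKM + 1) was 5.56 in line A at P13, 6.2 in line A at P35, 5.92 in line B at P35 and 6.11 in line B at P24, and 6.56 to 6.84 in the other later libraries. Line A went from 5.56 at P13 to 6.84 at P45, and line B from 6.56 at P12 to 6.76 at P46. Between these end points the list rose more in line A, where P13 was lowest, but not steadily, with 6.81 at P23 and 6.2 at P35. This list did not pass for the difference of slopes, so a rise particular to line A is not shown. Fibroblast and mesenchyme genes had a median of 0.06 (adjusted p = 0.00404, and adjusted p = 0.611 with an estimated correlation) and cell cycle genes of -0.04 (adjusted p = 0.00404, and adjusted p = 0.583 with an estimated correlation). Core pluripotency genes had a median of -0.07 and naive-state genes of 0.06 (adjusted p = 0.0361 for each, and adjusted p = 0.583 with an estimated correlation). Under quantile normalization these became 0.0534 and 0.0549, and naive-state genes had 0.0888 under median-of-ratios scaling. The other 14 testable lists did not pass camera, from 0.0892 for FGF and ERK target genes to 0.965; NODAL and TGF-beta target genes had a median of -0.02 with direction up.

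Of 10726 genes, limma called 0 rising and 0 falling with passage, against 156 and 107 at an unadjusted p under 0.05. Adjusted over the list alone, limma called 3 genes: SNRPN at 0.14 ± 0.03 and SYCP3 at 0.26 ± 0.07 rising and the p53 target BTG2 at -0.27 ± 0.06 falling, the last chosen after its values were seen. For the difference of slopes between lines, limma called 0 genes over all genes and 0 adjusted over the list alone, against 177 at an unadjusted p under 0.05. SOX2 slopes differed by 0.03 ± 0.06 (adjusted p = 0.999). The fibroblast and mesenchyme list had a lower fitted slope in line B, by a median of -0.14 (camera adjusted p = 0.01, and adjusted p = 0.85 with an estimated correlation), and no other list passed. The gap between lines at P10 enters this term, with a list mean log2(RPKM + 1) of 2.86 in line A and 4.03 in line B. Later libraries lay at 4.18 to 4.64 in line A and 4.06 to 4.44 in line B. They do not by themselves show a lower slope in line B. In the imprinted and p53 target lists the medians of the slope difference were -0.02 and -0.03 with direction up. In simulated data of this design 88% of slopes of 0.25 per 10 passages were recovered, and 38% of slope differences of that size. The simulated spread was independent between genes and libraries, without the differences that genes share between real libraries. These shares may therefore overstate recovery in the real data. There SYCP3 and BTG2, with slopes of about this size, had an adjusted p of 0.99 over all genes.

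**Figure D3:**
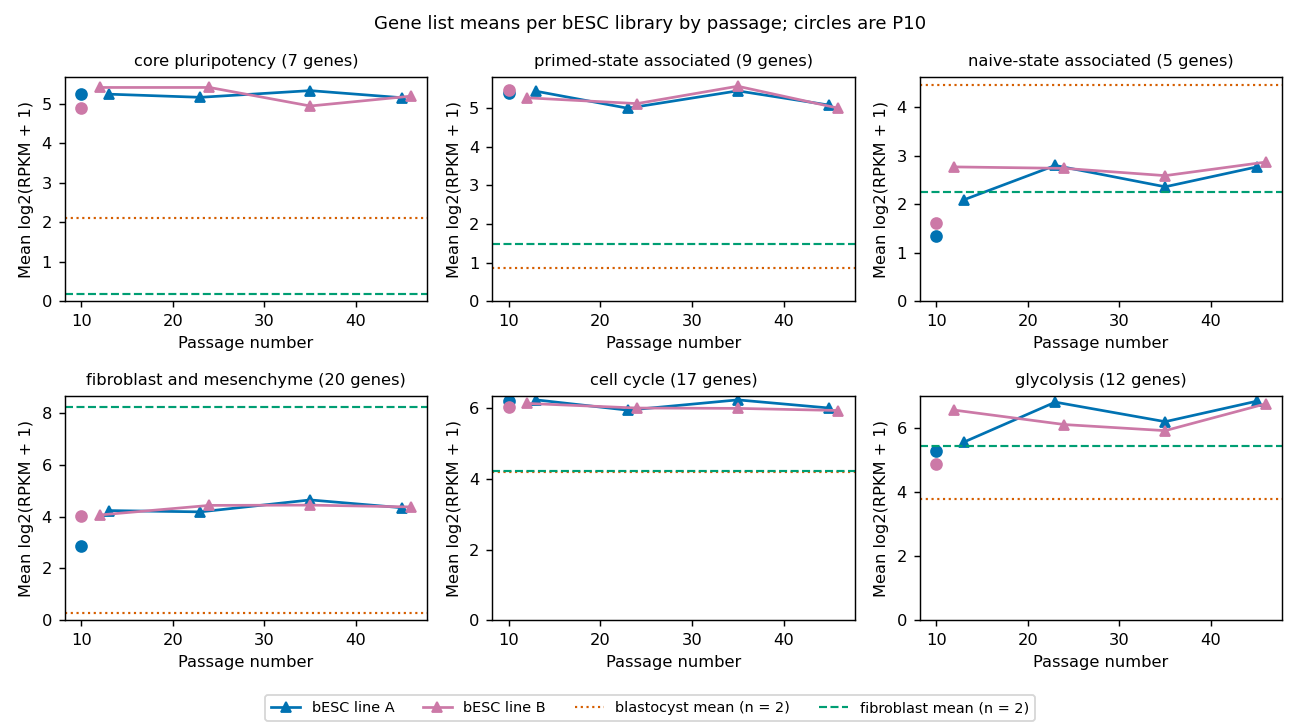
Mean log2(RPKM + 1) of 6 gene lists against passage number for lines A and B, with circles for P10 and triangles for later passages; horizontal lines give the means of the control groups (n = 2). The mean of 7 core pluripotency genes stays between 4.89 and 5.42 in all stem cell libraries, against 2.23 and 2 in blastocysts and 0.09 and 0.28 in fibroblasts. These are the members shared by both sets of files and expressed in the stem cells, with values as deposited. They leave out POU5F1 and NANOG, and also ZFP42 and DPPA2, which were higher in blastocysts. The panel therefore does not place the whole list above blastocysts.

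The last comparison sets the P10 libraries against the later ones, extrapolated to P10 by the passage slope. Stem cell libraries at P10 come from another set of files than the later ones, so passage and file set cannot be told apart here. Of 14 FGF and ERK target genes 8, and of 12 glycolysis genes 9, were called lower at P10, and with an estimated correlation neither list passed camera (adjusted p = 0.345 and 0.699). Among the members with the smallest adjusted p, IER3, an immediate early gene, stood at -2.74 ± 0.20 (SE, n = 2 against 8) relative to the median gene, the ERK phosphatases DUSP5 and DUSP6 at -1.82 ± 0.29 and -1.60 ± 0.16, and FOSL1 at -1.66 ± 0.20. The lactate transporter SLC16A3 stood at -2.85 ± 0.54 and TPI1 at -1.62 ± 0.40. PGAM1 measured 283 and 269 RPKM at P10, 1.23 to 3.07 in every later library and 128 to 346 in the controls, so it divides by file set and is not read as a change of glycolysis.

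FGF and ERK target genes fell in 8 of 14 cases and rose in 0 (relative median -1.34, adjusted p = 0.00542, and adjusted p = 0.345 with an estimated correlation; 7 of the calls held under every scaling). Glycolysis genes fell in 9 of 12 cases and rose in 1 (relative median -1.44, adjusted p = 0.032, and adjusted p = 0.699 with an estimated correlation; 5 and 1 under every scaling). Oxidative phosphorylation genes fell in 2 of 10 cases, COX6C at -0.66 ± 0.12 and NDUFB8 at -0.48 ± 0.11 (adjusted p = 0.0371, 0.104 and 0.107 under median-of-ratios scaling and quantile normalization, and adjusted p = 0.677 with an estimated correlation). Mitochondrially encoded genes rose in 2 of 6 cases, ND2 at 0.84 ± 0.18 and ND4L at 0.71 ± 0.17 (adjusted p = 0.014, 0.0349 and 0.0666 under the same scalings, and adjusted p = 0.509 with an estimated correlation). The p53 target list had 2 genes lower, BTG2 at -1.97 ± 0.20 and GADD45A at -1.47 ± 0.34 (camera 0.221), and the fibroblast and mesenchyme list 4 lower of 20, 2 of them under every scaling, with LOX at -1.60 ± 0.21 and DCN at -2.07 ± 0.41 (0.085; 0.0309 under quantile normalization and 0.0349 under median-of-ratios scaling). NODAL and TGF-beta target genes fell in 3 of 5 cases (0.085), naive-state genes in 2 of 5 (0.0548; 0.0403 under median-of-ratios scaling), with KLF4 at -1.74 ± 0.26, and WNT target and epithelial junction genes in 2 of 5 and 2 of 10 (0.221 and 0.286). In the core pluripotency list SALL4 rose by 0.62 ± 0.13 and UTF1 was called lower at -0.83 ± 0.28 (camera 0.998), a call (adjusted p = 0.0497) lost under median-of-ratios scaling (0.0701) and quantile normalization (0.0741), and SOX2 stood at -0.33 ± 0.11 as fitted, without a call (adjusted p = 0.0782). Trophectoderm, neural ectoderm and imprinted lists had 1 gene lower each, KRT18, GFAP and SNRPN, and the remaining lists none. The SNRPN call was lost under median-of-ratios scaling (0.161) and quantile normalization (0.442) and the GFAP call under quantile normalization (0.19).

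Of 10726 genes, limma called 247 higher and 1461 lower at P10 (14.5% higher), with a median gene at -0.11 log2. Under quantile normalization 792 were higher and 756 lower (51.2%, median 0.04) and under median-of-ratios scaling 552 and 949 (36.8%, median -0.04). Under all 3 scalings 246 were higher and 728 lower. Adjusted over the list alone, the lower counts were 9 for FGF and ERK target, 11 for glycolysis, 6 for fibroblast and mesenchyme, 4 each for oxidative phosphorylation and NODAL and TGF-beta target, 3 each for core pluripotency, naive-state, epithelial junction and p53 target, 1 for germline and 0 for imprinted. In the other lists, and for the higher counts, both adjustments gave the same numbers. The total of 1708 calls was 887 without line A at P10, 702 without line B at P12, 1066 without line B at P24 and 1127 without line B at P46.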

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

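The splits for passage slope and slope difference, the rescaling of the blastocyst comparison, the test of steps of log2 4 or more, both tests on mesenchymal genes and the line splits within passage stages were chosen after the result they bear on was seen; the line splits over all libraries, the count of detected features and the test over all called step genes were set before.

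More genes were higher than lower in P10 stem cells against blastocysts, 90.9% of the calls, in libraries where 2 features take 65.8% and 64.0% of the blastocyst RPKM. A candidate explanation is that these features push down every other blastocyst value. Each library was scaled to its summed RPKM without its own 2 most abundant features, which in the blastocysts are this pair. Then 5339 genes were higher and 2367 lower, or 69.3%. With 1 library left out at a time the share was 65.5% to 73.8%, above the bound of 55% set for that test. Leaving out the top 2 features of each library therefore lowered the excess without ending it under this scaling. The median gene still stood at 0.52 log2 there, and under quantile normalization 49.7% of the calls were higher. A remaining shift of scale is thus not excluded as the source of the rest. Detection of fewer features in the blastocysts is another candidate, since after that scaling they had 8818 and 8666 features at 1 RPKM or more against 9476 and 9540 in fibroblasts, 91.9%. That count does not separate a technical loss from a lower number of expressed genes in the embryo, so these cannot be told apart. A biological difference between embryo and cultured cells stays open and was not tested.

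The step between P10 and later libraries took in genes that vanish or appear, with RPL3 at 789 and 1128 RPKM at P10 and 0 to 0.062 in the later libraries, and PRMT1 at 0.042 and 0.102 against 326 to 353; both were chosen after their values were seen. A candidate explanation is that the 2 sets of files were made with different feature definitions. Of 44 genes with a step of log2 4 or more, 19 were higher and 25 lower at P10. In 97.7% of the 44, all 4 controls, which share the P10 file set, lay on the P10 side of all 8 later libraries. That explanation needs this, but a gene expressed only in later stem cells would give it too. MMP13 was listed at 0 in all 4 controls, with 0.226 and 8.08 RPKM at P10 and 43.8 to 147 later. For genes lower at P10 the share therefore does not separate the causes. RPL3, higher at P10, measured 241 to 1180 RPKM in the controls. Over all 1708 called genes the share was 53.5%, against 29.2% of 9018 genes not called, which leaves file set and passage as causes that cannot be told apart there. Early passage as a biological cause stays open, because P10 occurs in 1 file set.

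Mesenchymal genes were higher in P10 stem cells than in blastocysts, where 16 of 21 list members were called as deposited. That is near the share over all genes, of which 8583 of 11761 were called higher. Bovine cells with the profile of the 2 skin fibroblast lines could give this if they brought all their abundant transcripts. The called members would need a share of 2.88% of the fibroblast level in line A and 3.84% in line B. Of 58 genes at 100 RPKM or more in fibroblasts and under 1 in blastocysts, 11 lay under 0.77%, a bound tried first that left this open, and 4 lay under the stricter bounds set afterwards, 0.288% in line A and 0.384% in line B: FMOD, SST, ESM1 and ASPN, which were chosen after their values were seen. SST would need 20.3 RPKM in line A and 27.1 in line B and measured 0.142 and 0.114, and FMOD 6.38 and 8.51 and measured 0.064 and 0.026. These 4 genes, the lowest of the 58, fell short of what cells with exactly this profile would bring. The stricter bounds were set after the first had left the question open. All 58 genes had a median of 2.94%, near the needed share, and a range from 0.011% to 64.4% of the fibroblast level. The test therefore does not decide whether such cells are the whole source. Mouse feeder cells are a further candidate source: the same genes were higher in line B than in line A at P10 by a median log2 of 0.67, 48 of 58 in that direction, and their medians were 1.06% of the fibroblast level in line A and 4.54% in line B. No feeder profile was used, so feeder cells, such bovine cells and expression by the stem cells themselves cannot be told apart. VIM, among the top 2 features in fibroblasts, measured 674 RPKM at P10 and 6400 in fibroblasts, and COL1A1 47.9 and 1635.

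For the line difference, 100 splits of the 10 stem cell libraries into 5 and 5 were made, the real one included. As many genes as the 2 of the real lines were called in 2 of these 100 splits, a share under 0.05. These splits ignore passage stage, over which the lines vary together, so this share does not exclude chance. Across 10726 genes, the deviations of line A and line B at the same stage correlated at 0.775 at the first stage, P10. They correlated at 0.059 at the second stage, 0.565 at the third, 0.343 at the fourth and 0.745 at the fifth. These are correlations of deviations, not of the expression values themselves. The 16 splits that part the libraries of each stage are too few for a share under 0.05. Of these, 1, the real one, called as many, and the highest other called 0. With passage stage as a block limma called 0 genes between the lines, against 568 higher and 871 lower in line B at an unadjusted p under 0.05. Each stage holds 1 library of each line, so by design the block hardly moves the log2 differences of the called features. They were 2.15 ± 0.23 before and 2.15 ± 0.20 after for ENSBTAG00000001836 (adjusted p = 0.0643) and 1.18 ± 0.13 and 1.18 ± 0.14 (SE) for ENSBTAG00000046595 (0.107). The block fit had 4 residual degrees of freedom in place of 6. Of the 10 fits that left out a library, 7 called 0 genes. Over all libraries the highest other split called 1401 genes; it set both P10 libraries, line A at P13 and P35 and line B at P35 against the rest, which is a structure of the samples that does not follow the lines. With a real count of 0, all 100 splits for the slope difference (highest other 36) and all 100 reorderings of passage for the slope (highest other 102) gave as many, so chance is not excluded and these counts say nothing more.

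A library lay far from the others of its line in 10 of 92 groups of 5 libraries tested, 10.9%. Chance would give about 1 in 20 if all 5 came from 1 file set. Each group instead sets a P10 library of the first file set against later libraries of the second. Of the 10, 8 were P10 libraries, where passage and file set cannot be told apart, and 2 were later ones. Summed RPKM ran from 349527 to 435754 over the whole first set and from 475822 to 501373 over the second. In line A at P10, ND1 measured 3332 RPKM (nearest other library 2557), the summed RPKM was 349527 (nearest 475822) and 10708 features reached 1 RPKM (nearest 12155). In line B at P10, the summed RPKM was 365195 (nearest 478953), APOA1 measured 27.9 RPKM (nearest 63.8), CLDN6 58.2 (nearest 83.7), KLF4 3.05 (nearest 11.4) and LAMA1 1.68 (nearest 2.48). In line B at P35, GSC measured 5 RPKM (nearest 2.14), and at P46 the median RPKM of features at 1 or more was 9.27 (nearest 9.65). The fibroblast and mesenchyme list differed between the lines in its fitted slope, by a median of -0.14 log2 per 10 passages in line B against line A (interaction term, camera adjusted p = 0.01, and adjusted p = 0.85 with an estimated correlation). The P10 libraries enter this term, with list means of 2.86 in line A and 4.03 in line B. The later libraries, at 4.18 to 4.64 in line A and 4.06 to 4.44 in line B, do not by themselves show a lower slope in line B.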

How the results depend on the processing

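The alternatives chosen after seeing the data are the names shared by both sets of files, scaling without the 2 most abundant features, leaving out line A at P13 and P35, and the 8 later libraries alone; the others were set before. Against fibroblasts, the higher and lower counts stayed within 1.5 times under every alternative but the leave-one-out fits below: 5729 and 2848 with the 8 later libraries, 5350 and 2664 with all 10, 3867 and 2322 with a pseudocount of 0.1. The number of lists past the threshold fell to 0 in every comparison with an estimated correlation, a setting that allows for genes moving together. The count test on recovered reads was not run. Depth in reads is unknown, so no limit on low genes is given.

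Against blastocysts the higher and lower counts were 3508 and 3546 under quantile normalization, 5168 and 2481 under median-of-ratios scaling, and 5339 and 2367 without the 2 most abundant features; 11 lists passed under median-of-ratios scaling. Between the lines, 0 genes were higher in line B with no filter, with a filter at 5 RPKM, under quantile normalization, without the P10 term and without line A at P13 and P35, and 1 was lower without the mean-variance trend. The 8 later libraries alone called 2, of which 0 were among the 2 called with all 10. For passage, 3 lists passed under quantile normalization. The P10 step count was 2571 without line A at P13 and P35. The cause was not tested for these, except that both scalings and the removal of 2 features shift blastocyst values by construction.

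Leaving out 1 library at a time, counts against fibroblasts were 2426 to 3901 higher (2426 without line A at P10, 2695 without line B at P10) and 1691 to 2413 lower (1691 without fibroblast line 1), where the lone library of a group is assumed to vary like the others. Against blastocysts they were 7179 to 8578 higher and 433 to 882 lower (489 without pool 1, 433 without pool 2). Between the lines 0 to 2 were higher, with 2 without line B at P35, 1 without line A or line B at P10 and 0 in the other fits. Genes falling with passage numbered 0 to 1, with 1 without line A at P23. The P10 step count ran from 702 to 1774 (702 without line B at P12, 887 without line A at P10, 1066 without line B at P24, 1127 without line B at P46). Each such fit has fewer libraries.

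Of the named genes reported, 6 calls against fibroblasts, 6 against blastocysts and 8 of the P10 step kept their direction and lost the threshold under quantile normalization, and 3, 4 and 4 under median-of-ratios scaling. Among the genes reported, fitted changes, here without subtraction of the median gene, changed sign as follows. Against fibroblasts, PGK1 went from -1.03 to 0.51 with all 10 stem cell libraries, 0.89 with the 8 later ones, 0.51 with line means and 0.58 without line A at P13 and P35, and relative to the median gene from -1.26 to 0.13, 0.50, 0.13 and 0.24; the cause was not tested. GPI went to 0.10 with the 8 later ones but kept its direction relative to the median gene (-1.38 and -0.29). Against blastocysts, TET3 stood at -0.01 under quantile normalization, and relative to the median gene went from 0.25 to -0.01; the cause was not tested. PGK1 stood at -0.03 under median-of-ratios scaling. Under quantile normalization, median-of-ratios scaling and without the 2 most abundant features, ATP5A1 stood at -0.15, -0.20 and -0.15 and NDUFS1 at -0.57, -0.56 and -0.52. Relative to the median gene PGK1, ATP5A1 and NDUFS1 were negative as deposited (-0.08, -0.24 and -0.66) and under each of these settings, so their sign changes restate the shift of all blastocyst values.

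The replicate letters do not pair the groups: deviations of libraries with 1 letter correlated at -0.079, -0.099 and 0.187. With the letter as a block, 4056 and 2514 genes were called against fibroblasts and 8557 and 863 against blastocysts. Deviations of the lines at 1 passage stage correlated at 0.775 (P10), 0.059, 0.565, 0.343 and 0.745. With passage stage as a block 0 genes were called between the lines.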

Other observations

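All list tests in the next paragraphs were chosen after seeing the data, since the 3 lists were written once values of some members had been seen; p is adjusted over their 18 tests.

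Genes of cholesterol synthesis were higher in P10 stem cells than in blastocysts, where 10 of 11 members were called and 0 were lower, at a median log2 of 4.4 as deposited and 3.09 and 3.46 under quantile normalization and median-of-ratios scaling (camera adjusted p = 0.0348, and adjusted p = 0.632 with an estimated correlation). Against fibroblasts 2 members were higher and 2 lower, 1 and 2 under every scaling (0.553). Between the lines 0 members were called and the median was 0.13 in favour of line B (0.0122, and adjusted p = 0.524 with an estimated correlation). The list did not pass for the passage slope (0.34), its difference between lines (0.0621) or the P10 step (0.198).

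At P10, of 13 immediate early genes 12 were lower than later, 10 of them under every scaling, and 0 higher, at a median of -2.66 as deposited, where the median gene stood at -0.11 (9.77e-08, and adjusted p = 0.487 with an estimated correlation), and of 16 hypoxia-associated genes 9 were lower, 7 of them under every scaling, and 0 higher, at -1.21 (0.00145, and adjusted p = 0.524 with an estimated correlation). The P10 libraries differed on the immediate early list, with a mean log2(RPKM + 1) of 3.41 in line A and 1.98 in line B, against 4.68 to 5.48 in the later libraries. Among later passages hypoxia-associated genes had a slope of 0.11 per 10 passages (0.00145) and immediate early genes of -0.17 (0.00449), both with adjusted p = 0.524 with an estimated correlation and 0 genes called. The mean log2(RPKM + 1) of the hypoxia-associated list was 3.91 in line A at P13, 4.29 in line A at P35, 4.44 in line B at P35 and 4.64 in line B at P24, and 5.01 to 5.06 in the other later libraries. Line A went from 3.91 at P13 to 5.06 at P45, while line B stood at 5.03 at P12 and 5.01 at P46. Line A did not rise steadily, with 5.01 at P23 and 4.29 at P35. The slope difference between lines did not pass for this list (camera adjusted p = 0.122), so a rise particular to line A is not shown.

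In the other tests of these lists, against fibroblasts 1 hypoxia-associated gene was higher and 6 lower of 15 (0.0393) and 0 and 4 immediate early genes of 12 (0.0189), each with adjusted p = 0.524 with an estimated correlation. Against blastocysts 9 hypoxia-associated genes were called higher and 1 lower, 2 and 1 under every scaling (0.34), at a median of 0.87 as deposited and of -0.81 and -0.28 under quantile normalization and median-of-ratios scaling. There 3 immediate early genes were called higher and 1 lower, 1 and 1 under every scaling, with direction down (0.0434, and adjusted p = 0.524 with an estimated correlation), at a median of 1.14 as deposited, where the median gene stood at 1.43. Between the lines neither passed (0.132 and 0.739). The fitted slope difference of immediate early genes was 0.15 (0.0171, and adjusted p = 0.524 with an estimated correlation) and that of hypoxia-associated genes -0.07 (0.122). The gap between lines at P10 enters these terms, for immediate early genes with list means of 3.41 in line A and 1.98 in line B. Among later libraries that list went from 5.1 at P13 to 4.8 at P45 in line A. In line B it went from 5.48 at P12 to 4.81 at P46, so a higher slope in line B is not shown there.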
